A study of Mus musculus with 12 samples.

How the data were processed

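RNA sequencing values were taken for 12 mouse libraries from male C57BL/6J mice aged 18 weeks on normal chow. Epididymal adipose tissue (EAT) and inguinal adipose tissue (IAT) had been treated with collagenase I to separate adipocytes from stromal vascular cells (SVCs), the mixed non-adipocyte cells of the tissue. The 4 groups, EAT adipocytes, IAT adipocytes, EAT SVCs and IAT SVCs, held 3 libraries each. The labels do not say whether libraries came from separate or pooled mice, so that p values measure the spread between these libraries.

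The deposited tables hold gene values in FPKM (fragments per kilobase of exon and per 1 M mapped fragments) with lower and upper confidence bounds, 1 table per library. The submitters' processing notes name TopHat, Cufflinks and the mouse genome build GRCm38 (mm10), with no version of either tool, and the layout of the tables is that of Cufflinks. Read lengths, settings and the gene annotation were not given in the sources used here. Genes are identified by symbol and locus. The tables list 24890 features under 24358 symbols, and 273 symbols stand at more than 1 locus (805 features), which were kept apart. Of the features, 9 had a failed estimate in at least 1 library and were left out, among them Ebf2 and Lsp1. A match by symbol and chromosome to GENCODE vM21 gave a gene model for 23631 features, used for exon lengths only.

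The tables hold no read counts. The confidence bounds gave an estimate of the fragments behind each value, and 64.3% to 69.3% of the low values per library came to a whole number of fragments within 0.02. The estimated gene fragments were 14.2 M to 24.7 M per library, and relative depth ran from 0.776 to 1.31 of the first EAT adipocyte library. The median bound lay 21.1% to 27.3% from a value near 1 FPKM, 6.60% to 8.42% near 10 FPKM and 3.33% to 4.11% near 100 FPKM. These bounds cover counting error only.

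Values were transformed to log2(FPKM + 1). The 13175 features with at least 1 FPKM in at least 3 of the 12 libraries were fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with 4 group means and no block. The contrasts were IAT minus EAT in adipocytes, IAT minus EAT in SVCs, adipocyte minus SVC in EAT, adipocyte minus SVC in IAT, and the difference between both depot contrasts (interaction). All tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 within a contrast was called. Log2 differences are given with their standard error (SE) and FPKM means with their standard deviation (SD). Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

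Lists of genes for adipocyte functions, signalling pathways and the cell types of adipose tissue were fixed before the data were examined, 41 in number, as were the tests, the named-gene rule and the alternative settings. The 39 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The epididymal epithelium list had 1 measured member of 11 and the sex-linked list 4 of 5, so neither was tested. Named genes were, in each comparison, the 10 largest log2 differences in each direction among called genes with no overlap between the groups and a mean of at least 5 FPKM, up to 5 members of each list with the smallest p, and 12 reference genes. For the interaction they were the 10 genes with the smallest p. Predicted and microRNA models were left out of these rankings.

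Alternatives were other pseudocounts, no filter on low values, a filter on the mean, rescaling to TPM, median-of-ratios and quantile scaling, a fit on the compared groups alone, eBayes without trend, array weights, replicate number as a block, a 2-fold threshold and leaving out each library. Removal of a gene length trend per library was added after the data were seen. Tests for raw counts were not run, since the tables hold FPKM. The procedure was tested on simulated data of 13175 genes, with known changes of 3 sizes added to 66 or 67 genes each in every contrast. It called 68.7% to 74.6% of the changes of 0.5 (log2) in the comparisons of 2 groups and 43.3% in the interaction, 95.5% to 97.0% of the changes of 1 (83.6% in the interaction) and 100% of the changes of 2, with 8 to 11 false calls per contrast. The list test called the raised list and no other. The simulated genes were drawn independently of each other, so that this does not show how the list test behaves where genes are correlated.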

Results

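Transcript levels were measured by RNA sequencing in adipocytes and in SVCs of EAT, a visceral depot, and of IAT, a subcutaneous depot, in 3 libraries per group. Between 10726 and 12425 features reached 1 FPKM in a library, with an estimated 14.2 M to 24.7 M gene fragments behind them. Values below are means in FPKM ± SD of 3 libraries. Log2 differences, of log2(FPKM + 1), are given ± SE with limma's adjusted p. Libraries of a group correlated at r = 0.982 to 0.996 across genes, which are not independent replicates. EAT adipocyte replicate 1 stood lowest in this, at 0.982 and 0.985 with the others of its group.

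The fraction comparison asked which transcripts belong to adipocytes and which to the other cells of each depot. In EAT, Adipoq, which encodes the hormone adiponectin, was at 4149.7 ± 317 FPKM in adipocytes and 7.18 ± 0.648 FPKM in SVCs (log2 difference 8.99 ± 0.091, adjusted p = 1.6e-15). Adrb3, the adrenergic receptor that drives lipolysis, was at 454 ± 8.41 FPKM in adipocytes and 0.432 ± 0.0513 FPKM in SVCs (log2 difference 8.31 ± 0.11, adjusted p = 8.0e-15). Fbn1 (fibrillin), a matrix gene of fibroblasts, was lower in adipocytes, at 1.58 ± 0.394 FPKM in adipocytes and 161 ± 12.8 FPKM in SVCs (log2 difference -5.98 ± 0.12, adjusted p = 1.7e-13). Pi16, a marker of interstitial progenitors, was at 0.909 ± 0.237 FPKM in adipocytes and 108 ± 8.13 FPKM in SVCs. In IAT, Adipoq was at 3461 ± 218 FPKM in adipocytes and 21.7 ± 1.27 FPKM in SVCs (log2 difference 7.25 ± 0.091, adjusted p = 1.5e-14). The genes lowest in IAT adipocytes relative to SVCs included genes of lymphocytes. Ccr7, a homing receptor, was at 1.31 ± 0.118 FPKM in adipocytes and 95.5 ± 21 FPKM in SVCs (log2 difference -5.36 ± 0.15, adjusted p = 2.7e-12). Cd69, an activation marker, was at 1.09 ± 0.139 FPKM in adipocytes and 69.9 ± 12.1 FPKM in SVCs, and Lat, a T cell receptor adaptor, at 0.485 ± 0.0251 against 48.6 ± 12.9 FPKM.

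Genes of fat storage and fuel use were higher in adipocytes. The adipocyte identity list had 18 of 18 measured members higher and 0 lower in EAT adipocytes than in SVCs (18 and 0 adjusted over the list alone). For adipocyte identity camera gave an adjusted p = 3.8e-13, and an adjusted p = 0.0129 with an estimated correlation. The adipocyte identity list had 18 of 18 measured members higher and 0 lower in IAT adipocytes than in SVCs (18 and 0 adjusted over the list alone). For adipocyte identity camera gave an adjusted p = 8.2e-13, and an adjusted p = 0.0139 with an estimated correlation. Adipokines followed. The adipokines list had 15 of 16 measured members higher and 1 lower in EAT adipocytes than in SVCs (15 and 1 adjusted over the list alone). For adipokines camera gave an adjusted p = 2.8e-09, and an adjusted p = 0.00603 with an estimated correlation. Examples were Lep (661 ± 25.5 against 1.97 ± 0.165 FPKM), the satiety hormone leptin, and Retn (4243 ± 1073 against 10 ± 0.231 FPKM), resistin. The fatty acid oxidation list had 17 of 19 measured members higher and 2 lower in EAT adipocytes than in SVCs (17 and 2 adjusted over the list alone). For fatty acid oxidation camera gave an adjusted p = 5.1e-08, and an adjusted p = 0.0129 with an estimated correlation. The fatty acid oxidation list had 18 of 19 measured members higher and 1 lower in IAT adipocytes than in SVCs (18 and 1 adjusted over the list alone). For fatty acid oxidation camera gave an adjusted p = 5.9e-10, and an adjusted p = 0.00844 with an estimated correlation. Examples in IAT were Cpt2 (70.1 ± 4.87 against 5.58 ± 0.24 FPKM) and Hadh (286 ± 4.28 against 26.5 ± 0.458 FPKM), enzymes of mitochondrial fatty acid use. The fatty acid and triglyceride synthesis list had 19 of 20 measured members higher and 1 lower in EAT adipocytes than in SVCs (19 and 1 adjusted over the list alone). For fatty acid and triglyceride synthesis camera gave an adjusted p = 1.1e-10, and an adjusted p = 0.0534 with an estimated correlation. The fatty acid and triglyceride synthesis list had 19 of 20 measured members higher and 1 lower in IAT adipocytes than in SVCs (19 and 1 adjusted over the list alone). For fatty acid and triglyceride synthesis camera gave an adjusted p = 2.0e-11, and an adjusted p = 0.0455 with an estimated correlation. Its members Scd1, a desaturase, and Dgat2, which makes triglyceride, stood at 6061 ± 385 against 72 ± 4.32 FPKM and 1073 ± 24.9 against 17.8 ± 1.91 FPKM. The lipolysis list had 14 of 16 measured members higher and 1 lower in EAT adipocytes than in SVCs (14 and 1 adjusted over the list alone). For lipolysis camera gave an adjusted p = 1.4e-07, and an adjusted p = 0.0966 with an estimated correlation. The insulin signalling and glucose uptake list had 14 of 15 measured members higher and 1 lower in EAT adipocytes than in SVCs (14 and 1 adjusted over the list alone). For insulin signalling and glucose uptake camera gave an adjusted p = 1.4e-06, and an adjusted p = 0.18 with an estimated correlation. Slc2a4, the insulin-responsive glucose transporter, was at 70.3 ± 2.51 FPKM in adipocytes and 2.44 ± 0.162 FPKM in SVCs. The oxidative phosphorylation list had 27 of 27 measured members higher and 0 lower in EAT adipocytes than in SVCs (27 and 0 adjusted over the list alone). For oxidative phosphorylation camera gave an adjusted p = 1.1e-10, and an adjusted p = 0.206 with an estimated correlation.

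Matrix, interstitial progenitor and endothelial genes were higher in SVCs. The extracellular matrix list had 1 of 23 measured members higher and 21 lower in EAT adipocytes than in SVCs (1 and 21 adjusted over the list alone). For extracellular matrix camera gave an adjusted p = 4.7e-05, and an adjusted p = 0.244 with an estimated correlation. Examples were the gelatinase Mmp2 (2.41 ± 0.323 against 131 ± 6.33 FPKM) and elastin, Eln (2.4 ± 0.146 against 83.9 ± 2.25 FPKM). The DPP4+ interstitial progenitors list had 0 of 11 measured members higher and 11 lower in EAT adipocytes than in SVCs (0 and 11 adjusted over the list alone). For DPP4+ interstitial progenitors camera gave an adjusted p = 3.9e-04, and an adjusted p = 0.118 with an estimated correlation. Dpp4 itself was at 0.811 ± 0.173 FPKM in adipocytes and 27.9 ± 0.833 FPKM in SVCs. The endothelial cells list had 0 of 16 measured members higher and 16 lower in EAT adipocytes than in SVCs (0 and 16 adjusted over the list alone). For endothelial cells camera gave an adjusted p = 2.8e-04, and an adjusted p = 0.257 with an estimated correlation. The red blood cells list had 0 of 6 measured members higher and 6 lower in EAT adipocytes than in SVCs (0 and 6 adjusted over the list alone). For red blood cells camera gave an adjusted p = 0.0105, and an adjusted p = 0.257 with an estimated correlation. The lymphatic endothelium list had 0 of 5 measured members higher and 5 lower in EAT adipocytes than in SVCs (0 and 5 adjusted over the list alone). For lymphatic endothelium camera gave an adjusted p = 0.026, and an adjusted p = 0.118 with an estimated correlation. The lists of committed preadipocytes and mural cells were not called. The committed preadipocytes list had 5 of 11 measured members higher and 6 lower in EAT adipocytes than in SVCs (5 and 6 adjusted over the list alone). For committed preadipocytes camera gave an adjusted p = 0.708, and an adjusted p = 0.739 with an estimated correlation. For committed preadipocytes the test pointed up, while the median log2 difference was -0.80 and the mean -0.22. The mural cells list had 1 of 11 measured members higher and 9 lower in EAT adipocytes than in SVCs (1 and 9 adjusted over the list alone). For mural cells camera gave an adjusted p = 0.0762, and an adjusted p = 0.503 with an estimated correlation. The mural cells p ran from 0.0132 to 0.0924 over 15 alternatives and lay on the other side of 0.05 in 2.

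Immune genes were higher in EAT SVCs as well. The macrophages list had 0 of 20 measured members higher and 20 lower in EAT adipocytes than in SVCs (0 and 20 adjusted over the list alone). For macrophages camera gave an adjusted p = 1.4e-05, and an adjusted p = 0.0966 with an estimated correlation. The dendritic cells and MHC class II list had 0 of 14 measured members higher and 14 lower in EAT adipocytes than in SVCs (0 and 14 adjusted over the list alone). For dendritic cells and MHC class II camera gave an adjusted p = 1.7e-04, and an adjusted p = 0.106 with an estimated correlation. The NK and innate lymphoid cells list had 0 of 11 measured members higher and 11 lower in EAT adipocytes than in SVCs (0 and 11 adjusted over the list alone). For NK and innate lymphoid cells camera gave an adjusted p = 8.7e-04, and an adjusted p = 0.101 with an estimated correlation. The neutrophils and mast cells list had 0 of 11 measured members higher and 11 lower in EAT adipocytes than in SVCs (0 and 11 adjusted over the list alone). For neutrophils and mast cells camera gave an adjusted p = 6.3e-04, and an adjusted p = 0.181 with an estimated correlation.

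Transcripts of each fraction were also measurable in the other. In EAT adipocytes, endothelial genes stood at a median of 16.8% of their SVC level, macrophage genes at 13.5% and red blood cell genes at 4.31%. In IAT adipocytes these were at 19.1%, 4.0% and 4.75%. Adipocyte identity genes stood in the SVC libraries at a median of 0.342% of their adipocyte level in EAT and 1.2% in IAT.

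In total 11041 of 13175 genes differed between the fractions in EAT, 4093 higher and 6948 lower in adipocytes, 5395 of them by at least 2-fold. In IAT 11028 differed, 3921 higher and 7107 lower, 5309 by at least 2-fold. The groups did not overlap for 83.1% of the genes in EAT and 88.3% in IAT, where chance gives 10%. The median gene was at -0.31 (log2) in EAT and -0.34 in IAT. Median-of-ratios scaling moved it to -0.04 and -0.03, with 5301 higher and 5667 lower in EAT and 5331 and 5590 in IAT, so that the balance of directions is relative to FPKM.

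**Figure D1:**
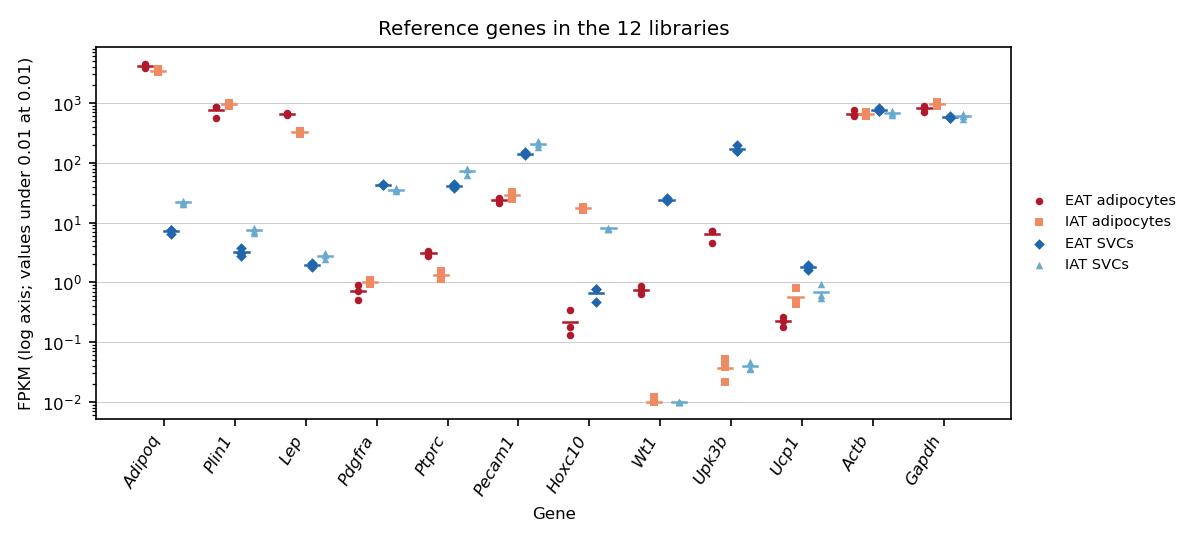
FPKM (log axis) of 12 reference genes in each of the 12 libraries, with a point per library and a bar at the group mean. Adipoq and Plin1 stand higher in adipocytes of both depots, Pdgfra and Ptprc higher in SVCs, Hoxc10 higher in IAT, and Wt1 and Upk3b higher in EAT.

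The adipocyte comparison asked how adipocytes of the inguinal depot differ from those of the epididymal depot. Hoxc10, a homeobox factor of posterior body position (chromosome 15, 102966796 to 102971897, mm10), was at 17.2 ± 1.11 FPKM in IAT and 0.217 ± 0.11 FPKM in EAT (log2 difference 3.91 ± 0.094, adjusted p = 1.3e-11). Cidea, a lipid droplet protein of brown and beige fat (chromosome 18, 67343564 to 67367794), was at 40.6 ± 4.16 FPKM in IAT and 2.12 ± 0.641 FPKM in EAT (log2 difference 3.75 ± 0.14, adjusted p = 6.8e-10). H2-Q10, a class I histocompatibility gene best known from liver, was at 113 ± 1.72 FPKM in IAT and 3.23 ± 0.282 FPKM in EAT (log2 difference 4.75 ± 0.09, adjusted p = 2.9e-12). Agt, the angiotensin precursor, was lower, at 24.7 ± 6.2 FPKM in IAT and 224 ± 3.02 FPKM in EAT (log2 difference -3.16 ± 0.14, adjusted p = 6.0e-09). Lep (leptin, chromosome 6, 29060221 to 29073876) was at 322 ± 16.3 FPKM in IAT and 661 ± 25.5 FPKM in EAT (log2 difference -1.04 ± 0.08, adjusted p = 7.3e-07).

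Thermogenic and oxidative genes were higher in IAT adipocytes. The brown and beige fat genes list had 12 of 14 measured members higher and 1 lower in IAT adipocytes (12 and 1 adjusted over the list alone). For brown and beige fat genes camera gave an adjusted p = 1.5e-11, and an adjusted p = 0.00264 with an estimated correlation. Examples were Cox8b (254 ± 23.6 against 29.3 ± 8.77 FPKM), a muscle-type subunit of cytochrome oxidase, Otop1 (4.76 ± 0.929 against 0.17 ± 0.0791 FPKM) and the transcription regulator Prdm16 (1.61 ± 0.241 against 0.302 ± 0.0972 FPKM). Ucp1, the uncoupling protein of brown fat, was at 0.57 ± 0.196 FPKM in IAT and 0.223 ± 0.039 FPKM in EAT (log2 difference 0.35 ± 0.10, adjusted p = 0.0135). Both means lay under 1 FPKM and below those of the SVCs, 0.698 FPKM in IAT and 1.80 FPKM in EAT. The Ucp1 call was lost without IAT adipocyte replicate 1 (adjusted p = 0.0635, the range over 17 alternatives being 0.00291 to 0.0635). The fatty acid oxidation list had 12 of 19 measured members higher and 1 lower in IAT adipocytes (15 and 1 adjusted over the list alone). For fatty acid oxidation camera gave an adjusted p = 4.9e-08, and an adjusted p = 0.0132 with an estimated correlation. Examples were Cpt1b (3.31 ± 0.407 against 0.573 ± 0.504 FPKM) and Acadl (186 ± 4.03 against 124 ± 11.5 FPKM), while Cpt1a (7.9 ± 0.509 against 14.3 ± 2.5 FPKM) was lower. The oxidative phosphorylation list had 15 of 27 measured members higher and 0 lower in IAT adipocytes (17 and 0 adjusted over the list alone). For oxidative phosphorylation camera gave an adjusted p = 1.0e-09, and an adjusted p = 0.31 with an estimated correlation. The differences of single members were small, such as Sdha (0.38 ± 0.064) and Uqcrc2 (0.41 ± 0.068) on the log2 scale. In EAT adipocyte replicate 1 these genes lay 0.468 (log2, median) above the other EAT libraries, more than the depot median of 0.36, so that the size of the difference depends on that library. The fatty acid and triglyceride synthesis list had 11 of 20 measured members higher and 2 lower in IAT adipocytes (11 and 2 adjusted over the list alone). For fatty acid and triglyceride synthesis camera gave an adjusted p = 1.8e-04, and an adjusted p = 0.223 with an estimated correlation. Examples were Elovl6 (15.7 ± 1.68 against 7.04 ± 0.756 FPKM) and Acss2 (113 ± 13.6 against 53.5 ± 5.79 FPKM), while Dgat2 (1073 ± 24.9 against 1624 ± 90.6 FPKM) was lower.

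Single genes outside these lists or at their edge differed too. Hcar2, the hydroxycarboxylic acid receptor that restrains lipolysis, was at 143 ± 10.2 FPKM in IAT and 32 ± 4.8 FPKM in EAT, and the pyruvate dehydrogenase kinase Pdk4 at 70.2 ± 5.42 FPKM in IAT and 20.1 ± 4.94 FPKM in EAT. Inmt (10.6 ± 1.12 against 162 ± 15.5 FPKM), a methyltransferase gene, and Hspb7 (1.39 ± 0.241 against 32.4 ± 2.02 FPKM), a small heat shock protein gene, were lower.

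Developmental and endocrine genes separated the depots in both directions. The positional transcription factors list had 15 of 34 measured members higher and 12 lower in IAT adipocytes (16 and 12 adjusted over the list alone). For positional transcription factors camera gave an adjusted p = 0.00142, and an adjusted p = 0.289 with an estimated correlation. Among those higher in IAT were Tbx15 (6.17 ± 0.499 against 0.0325 ± 0.00708 FPKM), Shox2 (6.36 ± 0.284 against 0.0889 ± 0.0238 FPKM) and Hoxa10 (5.51 ± 0.488 against 0.0911 ± 0.0424 FPKM). The TGF-beta and BMP signalling list had 2 of 21 measured members higher and 9 lower in IAT adipocytes (2 and 10 adjusted over the list alone). For TGF-beta and BMP signalling camera gave an adjusted p = 0.0385, and an adjusted p = 0.329 with an estimated correlation. The TGF-beta and BMP signalling p ran from 0.0121 to 0.0807 over 15 alternatives and lay on the other side of 0.05 in 2 (0.0807 without EAT adipocyte replicate 1 and 0.0567 without IAT adipocyte replicate 2). Nog, which encodes a BMP antagonist, was lower at 0.327 ± 0.178 against 5.78 ± 1.2 FPKM. The adipokines list had 3 of 16 measured members higher and 9 lower in IAT adipocytes (4 and 9 adjusted over the list alone). For adipokines camera gave an adjusted p = 0.32, and an adjusted p = 0.414 with an estimated correlation. The adipokines p ran from 0.0132 to 0.501 over 15 alternatives and lay on the other side of 0.05 in 1. The adipocyte identity list had 2 of 18 measured members higher and 8 lower in IAT adipocytes (2 and 8 adjusted over the list alone). For adipocyte identity camera gave an adjusted p = 0.502, and an adjusted p = 0.741 with an estimated correlation. The adipocyte identity p ran from 0.0225 to 0.636 over 15 alternatives and lay on the other side of 0.05 in 1. Examples were Npr3 (86.1 ± 3.85 against 194 ± 2.18 FPKM) and Adrb3 (245 ± 46.2 against 454 ± 8.41 FPKM), both lower.

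Genes used as markers of other cell types also differed between the adipocyte libraries. The macrophages list had 0 of 20 measured members higher and 20 lower in IAT adipocytes (0 and 20 adjusted over the list alone). For macrophages camera gave an adjusted p = 3.3e-16, and an adjusted p = 0.0109 with an estimated correlation. The mannose receptor Mrc1 was at 2.12 ± 0.0828 FPKM in IAT and 13.1 ± 0.993 FPKM in EAT (log2 difference -2.17 ± 0.075, adjusted p = 4.5e-10), and Folr2, of resident macrophages, at 6.44 ± 0.567 FPKM in IAT and 34.7 ± 2.28 FPKM in EAT. The chemokine genes Ccl3 (1.44 ± 0.294 against 28.8 ± 11.1 FPKM) and Ccl6 (7.44 ± 1.14 against 39.8 ± 4.03 FPKM) and the alternative-activation gene Retnla (79 ± 14 against 655 ± 261 FPKM) were lower as well. The mesothelial cells list had 1 of 14 measured members higher and 13 lower in IAT adipocytes (1 and 13 adjusted over the list alone). For mesothelial cells camera gave an adjusted p = 1.2e-08, and an adjusted p = 0.0256 with an estimated correlation. These genes mark the lining of the body cavity, among them Upk3b (0.0372 ± 0.0151 against 6.34 ± 1.59 FPKM) and Msln (0.0116 ± 0.0101 against 4.65 ± 0.35 FPKM). The adipose stem and stromal cells list had 11 of 17 measured members higher and 1 lower in IAT adipocytes (11 and 1 adjusted over the list alone). For adipose stem and stromal cells camera gave an adjusted p = 8.9e-09, and an adjusted p = 0.035 with an estimated correlation. Examples were the collagen gene Col1a1 (42.5 ± 3.64 against 17.9 ± 3.77 FPKM) and Dpt (744 ± 34 against 183 ± 27.1 FPKM), dermatopontin. Dpt was at 599 FPKM in IAT SVCs, below its level in IAT adipocytes, so that in IAT it is no marker of other cells. The dendritic cells and MHC class II list had 3 of 14 measured members higher and 9 lower in IAT adipocytes (4 and 9 adjusted over the list alone). For dendritic cells and MHC class II camera gave an adjusted p = 0.0722, and an adjusted p = 0.413 with an estimated correlation. The dendritic cells and MHC class II p ran from 0.0072 to 0.138 over 15 alternatives and lay on the other side of 0.05 in 6 (among them 0.023 without EAT adipocyte replicate 2 and 0.0258 without IAT adipocyte replicate 1). The class II gene H2-Aa was at 54.1 ± 11.6 FPKM in IAT and 158 ± 29.4 FPKM in EAT. Camera also called as higher in IAT Schwann cells (6 of 8 members, adjusted p = 1.2e-07), endothelial cells (8 of 16, 6.3e-06) and B cells (5 of 14 with 1 lower, 5.7e-04). The same held for red blood cells (3 of 6, 0.00461), T cells (2 of 17, 0.00461) and skeletal muscle (3 of 12, 0.00792). Of all 13175 genes tested, 1363 were higher, a share near that of the T cell genes. Median-of-ratios scaling lost the camera calls of T cells (adjusted p = 0.0694) and skeletal muscle (0.0509). None of these lists passed with an estimated correlation, the lowest adjusted p being 0.0927 for Schwann cells.

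Stress and interferon genes were higher in IAT adipocytes. The immediate early and dissociation response list had 14 of 18 measured members higher and 0 lower in IAT adipocytes (14 and 0 adjusted over the list alone). For immediate early and dissociation response camera gave an adjusted p = 2.1e-12, and an adjusted p = 0.0345 with an estimated correlation. These genes respond quickly to tissue digestion, among them Socs3 (360.0 ± 19.7 against 58.8 ± 13 FPKM) and Jun (286 ± 13.2 against 104 ± 22.5 FPKM). The interferon-stimulated genes list had 17 of 20 measured members higher and 0 lower in IAT adipocytes (17 and 1 adjusted over the list alone). For interferon-stimulated genes camera gave an adjusted p = 4.1e-12, and an adjusted p = 0.194 with an estimated correlation. Examples were Irf7 (23.6 ± 1.41 against 7.54 ± 0.846 FPKM) and Gbp2 (90.5 ± 17.4 against 24.5 ± 2.04 FPKM). Cxcl10, an interferon-induced chemokine gene, was at 344 ± 42.6 FPKM in IAT and 47.2 ± 5.88 FPKM in EAT (log2 difference 2.84 ± 0.18, adjusted p = 1.3e-07). Interferon-stimulated genes were higher in IAT SVCs too, 13 of 20 with 0 lower (camera adjusted p = 3.6e-06, and 0.323 with an estimated correlation). Camera did not call the interaction of this list (adjusted p = 0.0516).

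Altogether 4960 genes differed between the depots in adipocytes, 1363 higher and 3597 lower in IAT, 543 of them by at least 2-fold (205 and 338). The groups did not overlap for 48.3% of the genes, against 10% by chance. The median gene was at -0.10 (log2), and median-of-ratios scaling moved it to 0.0038 and the split to 2157 higher and 2163 lower, so that the excess of lower genes is relative to FPKM. Without EAT adipocyte replicate 1 the count was 6516, and without IAT adipocyte replicate 1 it was 3727.

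**Figure D2:**
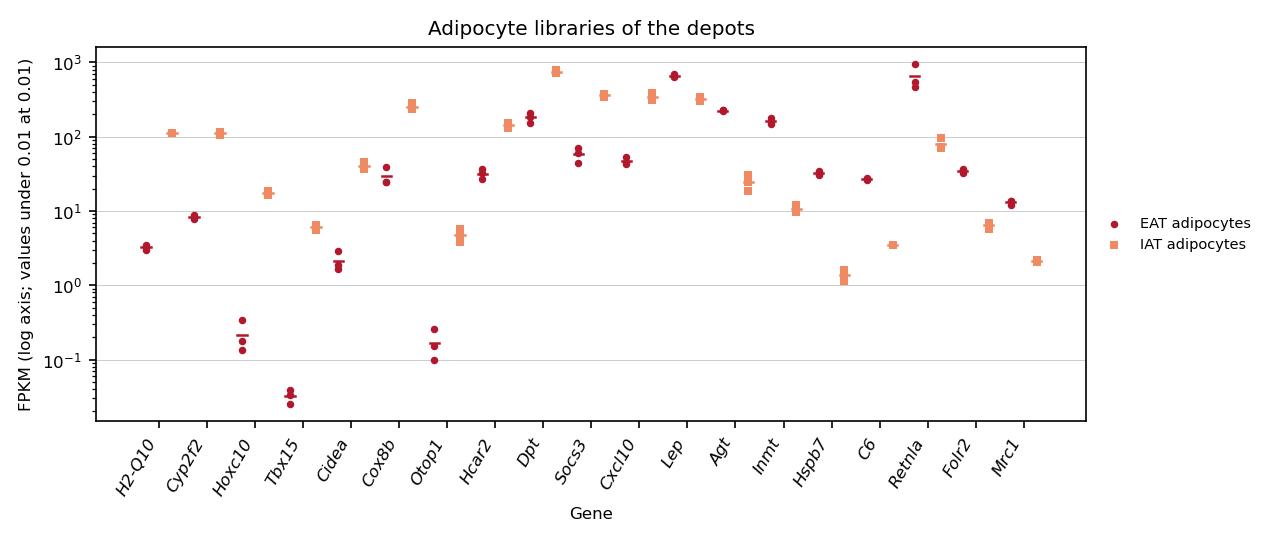
FPKM (log axis) of 19 named genes in the 6 adipocyte libraries, with a point per library and a bar at the group mean. Hoxc10, Tbx15, Cidea and Cox8b stand higher in all 3 IAT libraries than in any EAT library, and Lep, Agt, Inmt and Mrc1 lower.

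The SVC comparison asked the same of the other cells of the depots. Upk3b, a uroplakin of the mesothelium (chromosome 5, 136038496 to 136044993), was at 0.0393 ± 0.00555 FPKM in IAT and 171 ± 20.4 FPKM in EAT (log2 difference -7.36 ± 0.14, adjusted p = 1.2e-12). Msln, mesothelin (chromosome 17, 25748613 to 25754327), was at 0.101 ± 0.0415 FPKM in IAT and 93.7 ± 2.64 FPKM in EAT (log2 difference -6.43 ± 0.068, adjusted p = 1.0e-14). Tcf21, a transcription factor of visceral mesenchyme, was at 0.0581 ± 0.0507 FPKM in IAT and 60.4 ± 1.56 FPKM in EAT (log2 difference -5.86 ± 0.11, adjusted p = 1.4e-12). Higher in IAT was Mmp3, a matrix metalloproteinase, at 174 ± 3.59 FPKM in IAT and 2.11 ± 0.183 FPKM in EAT (log2 difference 5.82 ± 0.12, adjusted p = 2.5e-12). Cxcl14, a chemokine gene, was at 176 ± 20.3 FPKM in IAT and 12 ± 0.947 FPKM in EAT (log2 difference 3.76 ± 0.13, adjusted p = 1.7e-10).

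Mesothelial and epithelial genes were lower in IAT SVCs. The mesothelial cells list had 0 of 14 measured members higher and 14 lower in IAT SVCs (0 and 14 adjusted over the list alone). For mesothelial cells camera gave an adjusted p = 3.1e-19, and an adjusted p = 0.00616 with an estimated correlation. It was the only one of the 39 lists that passed in SVCs with an estimated correlation. Wt1 was listed at 0 in the IAT SVC libraries and at 23.8 FPKM in EAT. The keratinocyte and mammary epithelium list had 1 of 8 measured members higher and 5 lower in IAT SVCs (1 and 5 adjusted over the list alone). For keratinocyte and mammary epithelium camera gave an adjusted p = 0.00246, and an adjusted p = 0.086 with an estimated correlation. Its lower members were led by the keratins Krt7 (0.146 ± 0.109 against 18.9 ± 1.8 FPKM) and Krt8 (0.198 ± 0.185 against 19.8 ± 1.75 FPKM), which simple epithelia and mesothelium also express. Krt8 and Krt18 are held by the mesothelial list as well, so that the results of both lists are not separate.

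Lymphocyte genes were higher in IAT SVCs. The T cells list had 17 of 17 measured members higher and 0 lower in IAT SVCs (17 and 0 adjusted over the list alone). For T cells camera gave an adjusted p = 1.4e-19, and an adjusted p = 0.086 with an estimated correlation. Lck, a T cell kinase, was at 34.1 ± 6.49 FPKM in IAT and 3.78 ± 0.142 FPKM in EAT (log2 difference 2.86 ± 0.11, adjusted p = 5.8e-10), and other examples were Tcf7 (39.5 ± 9.38 against 3.17 ± 0.106 FPKM) and Cd8b1 (21.5 ± 6.12 against 0.638 ± 0.142 FPKM). The B cells list had 13 of 14 measured members higher and 0 lower in IAT SVCs (14 and 0 adjusted over the list alone). For B cells camera gave an adjusted p = 1.1e-14, and an adjusted p = 0.094 with an estimated correlation. Cd79a, of the B cell receptor, was at 93.1 ± 24.1 FPKM in IAT and 16.1 ± 0.597 FPKM in EAT (log2 difference 2.43 ± 0.13, adjusted p = 1.4e-08), and Fcmr, the IgM receptor, at 39.5 ± 8.07 FPKM in IAT and 4.1 ± 0.344 FPKM in EAT. Glycam1, an adhesion ligand of lymph node high endothelium, was at 17.2 ± 11.7 FPKM in IAT and 0.0184 ± 0.0319 FPKM in EAT (log2 difference 3.94 ± 0.34, adjusted p = 1.2e-06).

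The macrophage, neutrophil and inflammatory cytokine lists stood lower in IAT SVCs. The macrophages list had 0 of 20 measured members higher and 16 lower in IAT SVCs (0 and 17 adjusted over the list alone). For macrophages camera gave an adjusted p = 9.6e-05, and an adjusted p = 0.094 with an estimated correlation. Examples were Lyz2 (1041 ± 49.7 against 2334 ± 74.8 FPKM) and the growth factor receptor Csf1r (107 ± 3.34 against 209 ± 10.6 FPKM). The neutrophils and mast cells list had 0 of 11 measured members higher and 9 lower in IAT SVCs (0 and 9 adjusted over the list alone). For neutrophils and mast cells camera gave an adjusted p = 7.2e-04, and an adjusted p = 0.217 with an estimated correlation. The granule gene Ngp was at 0.0353 ± 0.0611 FPKM in IAT and 6.08 ± 1.56 FPKM in EAT. The inflammatory cytokines list had 3 of 23 measured members higher and 17 lower in IAT SVCs (3 and 18 adjusted over the list alone). For inflammatory cytokines camera gave an adjusted p = 0.00162, and an adjusted p = 0.449 with an estimated correlation. Saa3, an acute phase gene, was at 0.676 ± 0.269 FPKM in IAT and 19.5 ± 3.87 FPKM in EAT and Arg1 (0.438 ± 0.102 against 5.13 ± 0.635 FPKM) was lower, while the chemokine Ccl5 (155 ± 16.2 against 60.2 ± 5.62 FPKM) was higher. The dendritic cells and MHC class II list had 2 of 14 measured members higher and 6 lower in IAT SVCs (2 and 6 adjusted over the list alone). For dendritic cells and MHC class II camera gave an adjusted p = 0.619, and an adjusted p = 0.763 with an estimated correlation.

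Genes of nerve, muscle and fat were higher in the IAT SVC libraries. The Schwann cells list had 7 of 8 measured members higher and 0 lower in IAT SVCs (7 and 1 adjusted over the list alone). For Schwann cells camera gave an adjusted p = 1.0e-07, and an adjusted p = 0.086 with an estimated correlation. Mbp, a myelin protein gene, was at 76.3 ± 12.5 FPKM in IAT and 11.4 ± 0.207 FPKM in EAT (log2 difference 2.63 ± 0.13, adjusted p = 7.8e-09). The skeletal muscle list had 11 of 12 measured members higher and 1 lower in IAT SVCs (11 and 1 adjusted over the list alone). For skeletal muscle camera gave an adjusted p = 6.9e-14, and an adjusted p = 0.0675 with an estimated correlation. Examples were creatine kinase, Ckm (12.1 ± 0.648 against 0.0634 ± 0.0565 FPKM), and actin, Acta1 (24.3 ± 4.33 against 0.623 ± 0.0734 FPKM). Acta1 was not particular to SVCs, at 29.8 to 36.7 FPKM in EAT and 15.8 to 36.3 FPKM in IAT adipocyte libraries. Actn3 was lower, at 1.97 to 2.57 FPKM in IAT and 4.45 to 5.43 FPKM in EAT SVC libraries. Pvalb was listed at 0 in EAT and at 10.6 FPKM in IAT. The adipocyte identity list had 14 of 18 measured members higher and 2 lower in IAT SVCs (15 and 2 adjusted over the list alone). For adipocyte identity camera gave an adjusted p = 4.1e-08, and an adjusted p = 0.0675 with an estimated correlation. Examples were Adipoq (21.7 ± 1.27 against 7.18 ± 0.648 FPKM) and Car3 (129 ± 0.423 against 41.7 ± 2.23 FPKM). Adipocyte identity genes stood in SVC libraries at a median of 1.2% (IAT) and 0.342% (EAT) of their adipocyte level. More adipocyte RNA left in the IAT SVC libraries could therefore give this difference, which was not tested.

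Among stromal genes of the SVCs, differences went both ways. The adipose stem and stromal cells list had 9 of 17 measured members higher and 6 lower in IAT SVCs (9 and 6 adjusted over the list alone). For adipose stem and stromal cells camera gave an adjusted p = 0.0168, and an adjusted p = 0.325 with an estimated correlation. The adipose stem and stromal cells p ran from 0.00346 to 0.288 over 15 alternatives and lay on the other side of 0.05 in 1. Col3a1, a fibrillar collagen, was at 1776 ± 17.9 FPKM in IAT and 611 ± 14.8 FPKM in EAT (log2 difference 1.54 ± 0.086, adjusted p = 2.0e-08). Pi16 was higher too, at 318 ± 30.7 FPKM in IAT and 108 ± 8.13 FPKM in EAT. Fbn1 was lower in IAT, at 59.1 ± 6.84 FPKM in IAT and 161 ± 12.8 FPKM in EAT (log2 difference -1.44 ± 0.12, adjusted p = 7.5e-07).

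Altogether 5301 genes differed between the depots in SVCs, 1843 higher and 3458 lower in IAT, 772 of them by at least 2-fold (328 and 444). The groups did not overlap for 55.1% of the genes, against 10% by chance. The median gene was at -0.06 (log2). Median-of-ratios scaling moved the split to 2373 higher and 2631 lower, and rescaling to TPM moved the median to -0.16 and the split to 1436 and 4379.

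**Figure D3:**
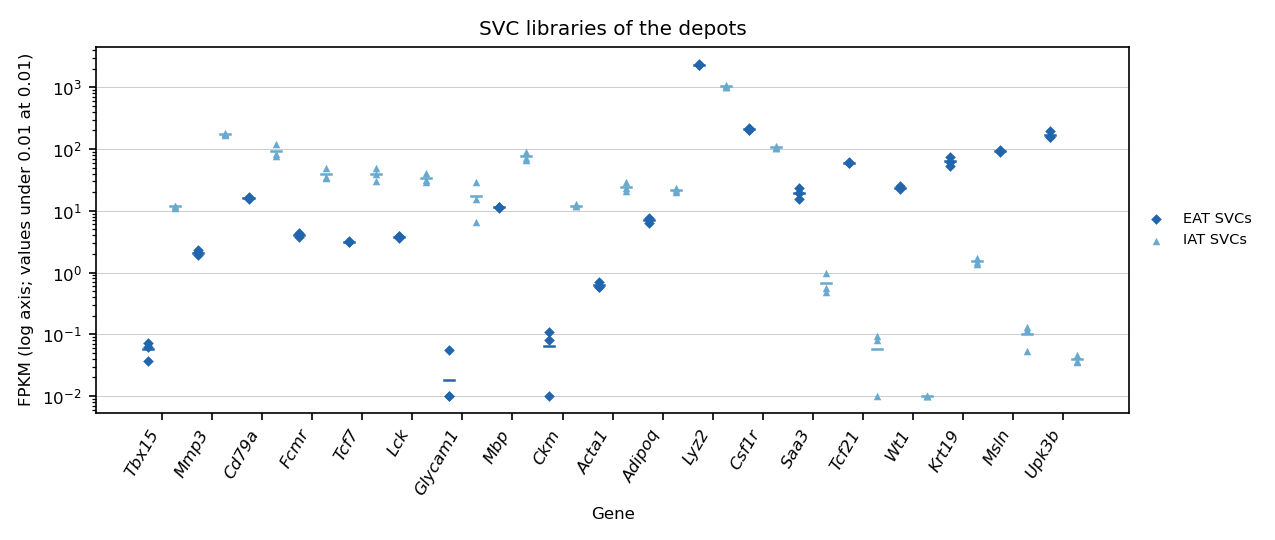
FPKM (log axis) of 19 named genes in the 6 SVC libraries, with a point per library and a bar at the group mean, values under 0.01 FPKM being drawn at 0.01. Upk3b, Msln, Wt1 and Tcf21 stand higher in all 3 EAT libraries, and Lck, Tcf7, Mbp and Tbx15 in all 3 IAT libraries.

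The depot differences of both fractions were then set against each other. Hoxc10 was higher in IAT in adipocytes (17.2 ± 1.11 against 0.217 ± 0.11 FPKM) and in SVCs (7.95 ± 0.225 against 0.673 ± 0.181 FPKM). Tbx15 was higher in IAT SVCs as well, at 11.7 ± 0.551 FPKM in IAT and 0.057 ± 0.0176 FPKM in EAT (log2 difference 3.59 ± 0.067, adjusted p = 1.2e-12). Thbs1, a matrix protein gene, was lower in IAT in both, at 155 ± 10.5 against 486 ± 77.3 FPKM in adipocytes and 35.4 ± 6.78 against 184 ± 14.6 FPKM in SVCs. C6, a complement gene, went opposite ways, at 3.47 ± 0.00983 against 26.8 ± 0.658 FPKM in adipocytes and 4.48 ± 0.39 against 0.953 ± 0.111 FPKM in SVCs. Of the 2450 genes called in both comparisons, 1985 (81.0%) had the same direction and 465 the opposite. Of these, 470 were higher in IAT in both, where 191 would be expected from independent calls, and 1515 lower, where 944 would be. Adipocyte libraries held SVC transcripts, in EAT at a median of 13.5% of the SVC level for macrophage genes and 4.97% for mesothelial genes. SVC depot differences may therefore recur in adipocyte libraries, and how much of the agreement this gives was not tested. The differences correlated across genes at Pearson r = 0.357 and Spearman rho = 0.323, genes not being independent replicates. The interaction test called 4281 genes with a different depot difference in the fractions, 931 of them by at least 2-fold.

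**Figure D4:**
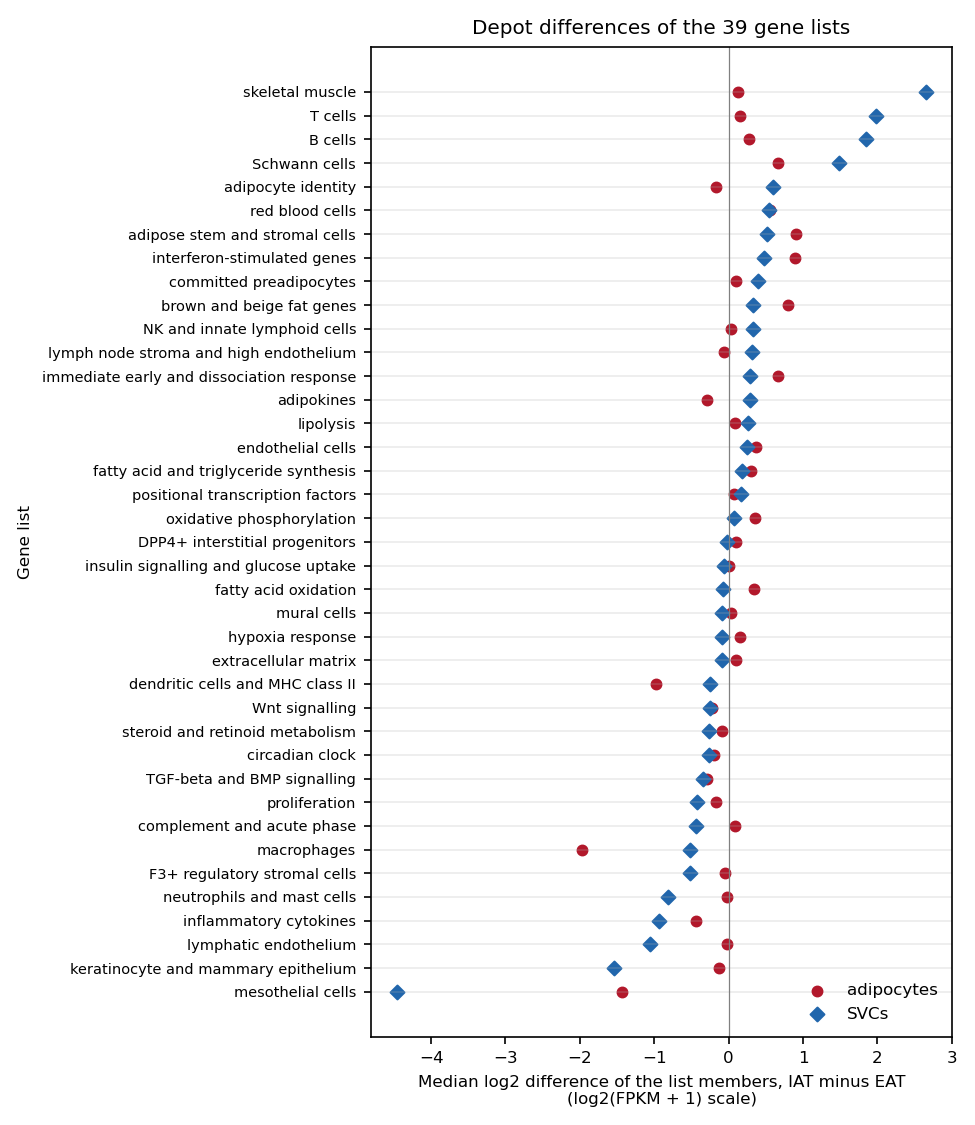
Median log2 difference of the members of each of the 39 tested gene lists, IAT minus EAT, in adipocytes (circles) and SVCs (diamonds). Mesothelial genes lie at -4.46 in SVCs and -1.43 in adipocytes, T cell genes at 1.98 and 0.16, and macrophage genes at -0.51 and -1.97.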

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

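The tests of technical explanations below were chosen after the results were seen, while the splits of the libraries were planned. Groups of 3 libraries were too small for a search for outlying values.

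The depot difference was not the same in both fractions for 4281 genes by the interaction test. The 10 genes with the smallest p differed, adipocytes minus SVCs on the log2 scale, by 4.73 ± 0.10 for Mup10, 3.48 ± 0.10 for Mup19, 4.25 ± 0.12 and 3.82 ± 0.11 for the Mup2 loci of chromosome 4 starting at 60578241 and 60135913, 3.95 ± 0.10 for Msln, 3.67 ± 0.091 for Upk1b, 3.83 ± 0.10 for Wt1, 4.68 ± 0.12 for Col6a5, -4.12 ± 0.10 for C6 and -3.29 ± 0.084 for Ckm. The Mup genes, which encode major urinary proteins, are close paralogs, and the division of fragments among them is uncertain. Msln, Upk1b, Wt1 and Col6a5 stood at no more than 0.325 FPKM in IAT in both fractions. With the 1 added before the logarithm, their differences therefore mostly reflect the EAT levels (Msln at 4.65 FPKM in adipocytes and 93.7 in SVCs, Wt1 at 0.755 and 23.8). This bears on the mesothelial list too, which holds Msln and Wt1. Of the reference genes, 5 were called in opposite directions, with differences of -1.73 ± 0.13 for Adipoq, -1.39 ± 0.11 for Lep, -1.63 ± 0.16 for Ptprc, 0.52 ± 0.12 for Pdgfra and 1.08 ± 0.14 for Ucp1. Adipoq was lower in IAT adipocytes (-0.26 ± 0.091) and higher in IAT SVCs (1.47 ± 0.091). Its SVC levels were 7.18 FPKM in EAT and 21.7 in IAT, against 4149.7 and 3461 in adipocytes. Those of Lep were 1.97 and 2.80, against 661 and 322. Adipocyte RNA left in the SVC libraries could give these SVC differences and those of the adipocyte identity list, which was not tested. The Adipoq call in adipocytes was lost in 7 of 18 alternatives, among them those without EAT adipocyte replicates 1 and 3 and IAT adipocyte replicates 1 and 3, with adjusted p from 0.00568 to 0.423. The Pdgfra calls were lost in 9 of 18 alternatives in adipocytes (0.00905 to 0.284) and 10 in SVCs (0.00235 to 0.181), among them those without any 1 adipocyte library except EAT replicate 2, or any 1 SVC library except IAT replicate 3. The SVC depot difference of the Mup2 locus starting at 60578241, not called, was called in 6 of 18 alternatives (5.35e-04 to 0.212), among them without IAT SVC replicate 2 (0.0394). That of the Mup2 locus starting at 60135913 was called in 4 (0.00196 to 0.365) and that of Mup19 in 1 (0.0318 to 0.801).

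Among the gene lists, 15 had a depot difference that differed between the fractions. The camera adjusted p of the interaction was 3.97e-08 for adipocyte identity, 0.00501 for adipokines, 0.0148 for brown and beige fat genes, 0.00285 for oxidative phosphorylation, 9.87e-05 for fatty acid oxidation, 2.18e-21 for mesothelial cells, 1.26e-05 for keratinocyte and mammary epithelium, and 7.39e-11 for both skeletal muscle and macrophages. It was 0.0277 for dendritic cells and MHC class II, 1.26e-14 for T cells, 4.46e-10 for B cells, 1.57e-04 for neutrophils and mast cells, 0.00119 for Schwann cells and 1.01e-05 for the immediate early list. With an estimated correlation the interaction passed for 5 of them (adjusted p = 0.046 for adipocyte identity, 0.046 for fatty acid oxidation, 0.00402 for mesothelial cells, 0.030 for keratinocyte and mammary epithelium and 0.030 for macrophages). It did not pass for the other 10 (adjusted p = 0.0578 for adipokines, 0.0882 for brown and beige fat genes, 0.613 for oxidative phosphorylation, 0.0578 for skeletal muscle, 0.301 for dendritic cells and MHC class II, 0.129 for T cells, 0.202 for B cells, 0.202 for neutrophils and mast cells, 0.244 for Schwann cells and 0.14 for immediate early and dissociation response, with an estimated correlation). Genes near 0 in 1 fraction or depot limit these tests, since the 1 added before the logarithm compresses their differences. In adipocytes of either depot 1 of 17 T cell genes reached 1 FPKM, and 1 (EAT) and 4 (IAT) of 14 B cell genes. Cd79a was at 2.55 FPKM in IAT and 0.492 in EAT adipocytes, with 93.1 and 16.1 in SVCs. In IAT the keratins Krt7 and Krt8 were near 0 in both fractions (Krt7 at 0 and 0.146 FPKM, against 0.952 and 18.9 in EAT). Abundance may therefore set part of the interaction of the T cell, B cell and keratinocyte lists, and how much was not tested. The keratinocyte list shares Krt8 and Krt18 with the mesothelial list, so that their interactions are not separate results. The T cell gene Cd247, above 1 FPKM in all groups, was at 2.235 FPKM in IAT and 1.603 in EAT adipocytes, with 30.84 and 10.91 in SVCs.

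The libraries of each pair of groups can be split in 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 4960, 5301, 11041 and 11028 in the real split against 0 in the highest other. The list test called 20, 22, 28 and 26 lists in the real splits against up to 19, 17, 25 and 23 in the others, many lists even where no gene passed. Each other split mixes both groups unevenly on either side. Part of the real difference therefore stays, while the mixing widens the spread. Neither the 0 genes nor the many lists show what chance alone would give. For the interaction, 2 of 100 splits gave as many genes, the real one with 4281 and 1 other with 5263. That other split set 3 adipocyte libraries against 3 SVC libraries, which is the structure of the samples, and the next ones called 3851 and 3609. Most splits mix the fractions within a group, which widens the spread there, so that this count does not settle whether chance can be excluded. For the genes shared by both depot comparisons in 1 direction, 1 of 100 splits gave as many, 1985 against at most 1 in the others. The mixing of fractions widens the spread here as well, so that this count says nothing about the directions.

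Macrophage genes were lower in IAT than in EAT adipocyte libraries, 20 of 20, the most abundant being Lyz2 at 270.0 against 43.4 FPKM and C1qb at 77.4 against 17.1. All 20 measured members reached 1 FPKM in EAT adipocytes, and 1 is held by another list. A share of the whole SVC suspension left in the EAT adipocytes, as measured by red blood cells, is argued against. In percent of the SVC level, 20 of the 20 genes stood above the highest red blood cell gene. The share was not peculiar to macrophages, since endothelial (16.8%) and mural cell genes (14.6%) stood as high in median in EAT, while mesothelial (4.97%) and stromal genes (5.17%) stood lower. An equal carry-over in both depots is argued against as well, since 18 macrophage genes had a depot difference below both -1 and 2 times the median of these genes in SVCs. Macrophages carried with floating EAT adipocytes, at a median of 13.5% of their SVC level, cannot be told apart from macrophages bound more closely to adipocytes in EAT, because no library separates them. The depot itself stays an open explanation, untested.

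T cell and B cell genes were higher in IAT than in EAT SVC libraries, Cd79a at 93.1 against 16.1 FPKM and Tcf7 at 39.5 against 3.17. More blood in the IAT suspension is argued against as the whole cause by the red blood cell genes, if lymphocytes follow red blood cells. Their median log2 difference of 0.538 stayed below the lower quartile of the lymphocyte genes. Blood may still contribute, since 3 of 6 red blood cell genes were higher and 0 lower in IAT SVCs (camera adjusted p = 0.0168, and 0.347 with an estimated correlation). A smaller share of mesothelial cells that raises all other types alike is argued against by 16 of 20 macrophage genes that were lower. Whether it contributes in part was not tested. Lymph node tissue, which lies within inguinal fat, may contribute, with 3 of the 6 measured lymph node genes higher in IAT (Cxcl13 at 42.1 against 5.0 FPKM, Ccl19 at 40.6 against 21.1, and Glycam1) and 2 lower (Chst4 and Enpp2). It cannot be told apart from lymphocytes of the fat itself, since the list is small and mixed, and the labels state no removal of the node. Of those 6 genes, 1 is held by another list, and 3 reached 1 FPKM in adipocytes of either depot.

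EAT adipocyte replicate 1 stood apart from its group, as the lower correlations show. Genes with under 1000 bases of exon lay 0.418 (log2, median) above the other replicates, against at most 0.124 in either direction in the 9 libraries of the other groups, which is consistent with a gene length trend as part of what sets it apart. By rank the trend was about as close in IAT SVC replicate 3 (Spearman rho of deviation and exon length 0.501, against -0.53 in EAT adipocyte replicate 1), so that only its size sets this library apart. The rho of 0.541 in EAT adipocyte replicate 2 is no separate evidence, since its deviation was taken against a mean that holds replicate 1. More SVCs in that library are argued against, since the largest median deviation of macrophage, stromal and mesothelial genes was 0.0856. With the trend removed the adipocyte depot comparison called 5686 genes, and without the library 6516, and no biological explanation was tested for it.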

How the results depend on the processing

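The removal of a gene length trend was chosen after the results were seen, and the other alternatives before. The gene counts of the 4 comparisons and the interaction stayed within 1.5 times under other pseudocounts, filters, scalings and fits. Which genes were called changed more. Of 4960 genes in the adipocyte depot comparison, 3525 were also called with median-of-ratios scaling and 3341 with quantile scaling. In the SVC depot comparison 4473 and 4622 of 5301 were. A 2-fold threshold left 543 genes (adipocytes, depots), 772 (SVCs, depots), 5395 (EAT, fractions) and 5309 (IAT, fractions), by its own construction. With an estimated correlation the list tests called 6, 1, 3 and 5 lists in place of 20, 22, 28 and 26. Only camera's setting for the correlation between genes was changed here, so that most list calls rest on its low preset value. Which value is right for these lists was not tested. With fry, which does not compare a list with other genes, the adipocyte depot comparison called 31 lists. Fry turned the direction of complement and acute phase in adipocytes between depots (adjusted p = 1.57e-04), of lymph node genes in SVCs between depots (0.0436), of the circadian clock between fractions in EAT (1.81e-05) and IAT (0.00197), and in IAT of positional transcription factors (1.8e-04) and committed preadipocytes (9.63e-04), and the cause was not tested. Of 150 single-gene results, none turned direction in any alternative, and 27 of 2771 values lost and 11 gained the call. Named genes other than the reference genes were picked by size or p in these same data, so that reversals were unlikely from the start. Of 156 list results, 22 of 2336 values lost and 27 gained it outside the other list tests. Leaving out each library gave 3727 to 6516, 4259 to 4779, 10669 to 11234 and 10663 to 10741 genes in the comparisons, 3513 to 5300 in the interaction, 19 to 22, 21 to 24, 27 to 28 and 26 lists, and 79.9% to 83.4% of shared genes in the same direction, where scaling gave 78.0% to 85.5%. Quantile scaling put 48.5%, 50.2%, 51.3% and 51.3% of called genes in the higher direction, against 27.5%, 34.8%, 37.1% and 35.6%. The deviations of equal replicate numbers correlated at -0.31 to 0.37 across genes. In 0 of 6 pairs of groups did every library correlate best with its own number. The deviations also followed exon length (Spearman rho from -0.53 to 0.541), so that this check cannot exclude that equal numbers share a mouse. With the number as a block the counts were 4796, 5205, 11037, 11010 and 4114. Near 1 FPKM the counting bounds of 21.1% to 27.3% limit what can be seen.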

Other observations

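The tests of this part were chosen before the results were seen, on lists fixed beforehand, except the principal components and the comparison of equal values between libraries. Between depots, complement genes went both ways. The complement and acute phase list had 3 of 14 measured members higher and 3 lower in IAT adipocytes (3 and 3 adjusted over the list alone). For complement and acute phase camera gave an adjusted p = 0.491, and an adjusted p = 0.645 with an estimated correlation. For complement and acute phase the test pointed up, while the median log2 difference was 0.08 and the mean -0.17. C3, the central complement component, was at 166 ± 18.3 FPKM in IAT and 61.1 ± 15.8 FPKM in EAT. In SVCs the acute phase genes Lcn2 and Hp were lower in IAT, at 1.8 ± 0.339 against 17.9 ± 1.49 FPKM and 22.9 ± 1.69 against 102 ± 6.29 FPKM. The Wnt signalling list had 2 of 16 measured members higher and 8 lower in IAT adipocytes (2 and 8 adjusted over the list alone). For Wnt signalling camera gave an adjusted p = 0.256, and an adjusted p = 0.399 with an estimated correlation. Axin2, a target of the pathway, was at 3.2 ± 0.427 FPKM in IAT and 9.92 ± 1.92 FPKM in EAT, and the agonist Rspo1 at 0.165 ± 0.0133 FPKM in IAT and 2.27 ± 0.538 FPKM in EAT. The Wnt signalling list had 5 of 16 measured members higher and 8 lower in IAT SVCs (5 and 8 adjusted over the list alone). For Wnt signalling camera gave an adjusted p = 0.441, and an adjusted p = 0.519 with an estimated correlation. Here Rspo1 (2.18 ± 0.499 against 55.9 ± 3.55 FPKM) was lower, while Wnt2 (5.25 ± 0.523 against 0.539 ± 0.143 FPKM) and Dkk2 (5.28 ± 0.574 against 0.517 ± 0.0913 FPKM) were higher. The steroid and retinoid metabolism list had 3 of 17 measured members higher and 9 lower in IAT SVCs (4 and 9 adjusted over the list alone). For steroid and retinoid metabolism camera gave an adjusted p = 0.0409, and an adjusted p = 0.347 with an estimated correlation. The steroid and retinoid metabolism p ran from 0.00862 to 0.073 over 15 alternatives and lay on the other side of 0.05 in 5 (among them 0.073 without EAT SVC replicate 3 and 0.0592 without IAT SVC replicate 2). In adipocytes the retinaldehyde dehydrogenase Aldh1a1 was at 54.6 ± 1.5 FPKM in IAT and 120.4 ± 2.02 FPKM in EAT. The hypoxia response list had 6 of 12 measured members higher and 1 lower in IAT adipocytes (6 and 1 adjusted over the list alone). For hypoxia response camera gave an adjusted p = 0.00843, and an adjusted p = 0.223 with an estimated correlation. The hypoxia response p ran from 0.00292 to 0.0892 over 15 alternatives and lay on the other side of 0.05 in 1. Adm, a vasodilator peptide gene, was at 45.1 ± 6.33 FPKM in IAT and 21.3 ± 3.87 FPKM in EAT.

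Cell type genes not described so far also went both ways in SVCs. The proliferation list had 2 of 14 measured members higher and 9 lower in IAT SVCs (2 and 9 adjusted over the list alone). For proliferation camera gave an adjusted p = 0.0636, and an adjusted p = 0.462 with an estimated correlation. The proliferation p ran from 0.030 to 0.174 over 15 alternatives and lay on the other side of 0.05 in 4 (among them 0.030 without EAT SVC replicate 2 and 0.0492 without IAT SVC replicate 1). Mki67, a cell cycle marker, was at 1.96 ± 0.196 FPKM in IAT and 4.8 ± 0.77 FPKM in EAT. The mural cells list had 3 of 11 measured members higher and 3 lower in IAT SVCs (3 and 3 adjusted over the list alone). For mural cells camera gave an adjusted p = 0.627, and an adjusted p = 0.82 with an estimated correlation. For mural cells the test pointed up, while the median log2 difference was -0.083 and the mean 0.048. The smooth muscle genes Acta2 (86.1 ± 8.84 against 37.6 ± 1.1 FPKM) and Myh11 (30.7 ± 4.49 against 17.6 ± 1.61 FPKM) were higher. The committed preadipocytes list had 5 of 11 measured members higher and 1 lower in IAT SVCs (6 and 1 adjusted over the list alone). For committed preadipocytes camera gave an adjusted p = 0.0122, and an adjusted p = 0.094 with an estimated correlation. The committed preadipocytes p ran from 0.00559 to 0.111 over 15 alternatives and lay on the other side of 0.05 in 1. Dlk1, a preadipocyte gene, was at 3.67 ± 0.48 FPKM in IAT and 0.913 ± 0.153 FPKM in EAT. The F3+ regulatory stromal cells list had 2 of 8 measured members higher and 4 lower in IAT SVCs (2 and 4 adjusted over the list alone). For F3+ regulatory stromal cells camera gave an adjusted p = 0.297, and an adjusted p = 0.415 with an estimated correlation. Mgp was lower, at 132 ± 16.2 FPKM in IAT and 488 ± 12.8 FPKM in EAT. The NK and innate lymphoid cells list had 6 of 11 measured members higher and 4 lower in IAT SVCs (6 and 4 adjusted over the list alone). For NK and innate lymphoid cells camera gave an adjusted p = 0.306, and an adjusted p = 0.512 with an estimated correlation. For NK and innate lymphoid cells the test pointed up, while the median log2 difference was 0.32 and the mean -0.038. The alarmin receptor Il1rl1 (2.98 ± 0.12 against 9.32 ± 0.679 FPKM) was lower and Tbx21 (4.64 ± 0.165 against 2.46 ± 0.131 FPKM) higher. The lymph node stroma and high endothelium list had 3 of 6 measured members higher and 2 lower in IAT SVCs (3 and 2 adjusted over the list alone). For lymph node stroma and high endothelium camera gave an adjusted p = 0.297, and an adjusted p = 0.415 with an estimated correlation. Of endothelial genes, 6 of 16 were higher and 0 lower in IAT SVCs (camera adjusted p = 0.00205, and 0.367 with an estimated correlation). Of lymphatic endothelium genes, 0 of 5 were higher and 3 lower (camera adjusted p = 0.0129, and 0.094 with an estimated correlation). The circadian clock list had 0 of 16 measured members higher and 7 lower in IAT SVCs (0 and 8 adjusted over the list alone). For circadian clock camera gave an adjusted p = 0.112, and an adjusted p = 0.367 with an estimated correlation. Bhlhe40, a clock repressor, was at 58.7 ± 5.73 FPKM in IAT and 106 ± 6.21 FPKM in EAT. In adipocytes the output genes Hlf (4.0 ± 0.442 against 1.41 ± 0.302 FPKM) and Dbp (42.7 ± 1.83 against 25.1 ± 2.33 FPKM) were higher in IAT.

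The first principal component of the 12 libraries held 85.9% of the variance, the second 7.59% and the third 3.21%. No pair of libraries shared more than 0.00584% of equal values among genes above 0.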
